A study of Anopheles coluzzii with 12 samples.

How the data were processed

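Small RNA libraries had been prepared from total RNA of heads and thoraxes of adult female and male Anopheles coluzzii of the MOPTI colony. Per the labels' protocols, RNA was extracted with TRIzol in 3 biological replicates of 30 mosquitoes each. Libraries were made with a TruSeq small RNA kit and sequenced on a HiSeq4000 as 50-bp single reads, per the labels. The labels give the size range as 18 to 32 nt in the sample descriptions and as 18 to 30 nt in the protocol. Trim Galore and Bowtie are named in the submitters' processing notes without versions. The genome build, annotation, counting tool, size classes counted and treatment of reads that match several places are not given in the sources used here. Elements of a TE family share sequence, so reads of single TEs are uncertain where related copies could share them.

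The authors deposited raw read counts per feature, 1 table per library, per the file headers. The header says that the counts hold both without naming of what, and sense and antisense reads are not separated, so strand shares and strand-specific tests were not run. Each table lists the same features (1674 gene IDs, 2790 Merged loci and 504 TE consensus sequences whose names hold their class). The reference table at hand (assembly AcolN3) matched 0 of the gene IDs, so no gene names are given. Counted reads ranged from 73819 to 565246 per library, and a count of 0 allows up to 40.6 CPM in the shallowest and 5.31 CPM in the deepest library (3 counts of the total). These floors and the 95% exact intervals of read ratios cover counting error alone, since reads without molecular identifiers are not independent molecules.

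Groups came from the sex and tissue in the labels. The labels number replicates 1 to 3 in each group without saying what a number shares. Residuals of female head and female thorax libraries with the same number correlated in all 3 pairs (0.197, 0.250 and 0.301, each over 0.1), although 2 of the 3 and not pair 1 matched best with their own number, so those numbers were taken to pair the female libraries, from the data and not the design. Male head and male thorax libraries correlated less (0.0627 to 0.166) but each matched best with its own number, and they were not taken as paired in the tests by tissue. All pairs of replicates differed by more than sampling noise (chi-square per degree of freedom from 6.37 to 64.6), so none was a repeated deposit. The main test was edgeR 4.0.16 (R 4.3.3) with filterByExpr, TMM factors, robust quasi-likelihood fits of all 12 libraries and 1 coefficient per group, which tested 1166 features (1034 gene features, 24 Merged loci and 108 TEs). The 4 pairwise contrasts were female against male in each tissue and head against thorax in each sex, and the interaction was the sex difference in head minus that in thorax. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. TMM factors ranged from 0.422 to 3.02 and were 0.817 or above in females and 0.758 or below in males, so that the scaling moved with sex. Log2 fold changes were therefore also set beside those with library totals and with TE reads as library size. Shares of classes and ratios of summed reads were compared by two-sided exact permutation tests, within strata of tissue or sex where all 12 libraries entered.

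Feature lists were fixed before the data were examined. Of the 14 lists, those of TE classes had members, and the lists of microRNAs of muscle, neural, gut, ovary and let-7 groups, of satellites and of structural RNAs had 0 members among the features. Helitrons had 0 tested members, SINEs 1 and Copia 3. Lists with at least 5 tested members (Gypsy, BEL-Pao, LINE and DNA transposons) were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry (limma 3.58.1). Named features followed a rule fixed beforehand. It took, per comparison and direction, the 10 largest changes among features past the threshold with no overlap between the groups and a mean of at least 10 CPM in the higher group (for the interaction, the 5 largest), the 10 most abundant features, and the 3 most abundant members of each list. Because gene IDs could not be paired with names, at most 2 per direction and comparison are printed.

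Alternatives planned beforehand were DESeq2 size factors, library totals, no filter, a mean of at least 10 CPM, DESeq2 1.42.0 (Wald test), limma-voom, a block for replicate number, each replicate left out, and fits of the compared groups alone. Added after the data were seen were scaling to TE reads or to reads outside the 2 dominant features, a replicate block among the female libraries alone, permutations that keep libraries of the same number together, a list of all TEs, leaving out the 2 libraries under 100000 reads, the gene-to-TE ratio, TE class composition and single TEs relative to TE reads. The scripts were tested on simulated counts, of which 623 features passed the filter. The counts were drawn with the real means and dispersions and with library sizes multiplied by the TMM factors. The recovery rates therefore hold for those sizes and not for the real ones. Changes of 4-fold were recovered for 63.6% of features in the head contrast and 89.4% in the thorax contrast, and of 2-fold for 7.14% and 26.8%. Summaries and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.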

Results

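Small RNAs were sequenced from the heads and thoraxes of adult females and males of the MOPTI laboratory colony of Anopheles coluzzii, a mosquito that transmits malaria. The design asks how the small RNAs of somatic tissues differ between the sexes and between body parts. Each of the 4 groups (female head, female thorax, male head and male thorax) held 3 biological replicates, and each replicate pooled 30 mosquitoes. The read counts covered 1674 gene IDs, 504 consensus sequences of transposable elements (TEs, mobile DNA that Piwi-interacting and small interfering RNAs silence) and 2790 loci named Merged. The files do not pair the gene IDs with names, so gene features appear below mainly as groups. Counted reads per library ranged from 73819 in male head replicate 1 to 565246 in female thorax replicate 2. They came to 138829, 328267 and 145672 in female head, 446237, 565246 and 96349 in female thorax, 73819, 293724 and 132688 in male head, and 316854, 486673 and 400080 in male thorax. These totals cover the listed features alone, and the full sequencing depth per library is not given in the sources used here. No read was counted in any library for 1858 features, of which 1808 were Merged loci.

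A pair of features dominated every library. The gene feature ACMO_005053 took 28.9% to 75.3% of a library's reads and the most abundant Merged locus took 17.3% to 40.1%. Together they held 73.7% ± 7.58 (SD, n = 3) of the reads in female head, 68.5% ± 8.50 (SD, n = 3) in female thorax and 85.1% ± 8.98 (SD, n = 3) in male head, and from 57.6% to 81.9% in the 3 male thorax libraries. TEs held 8.15% ± 2.41 (SD, n = 3) of all reads in female head, 9.91% ± 0.845 (SD, n = 3) in female thorax, 7.26% ± 5.0 (SD, n = 3) in male head and 15.6% ± 7.40 (SD, n = 3) in male thorax. None of the 10 class shares tested differed in any of the 4 pairwise comparisons after Benjamini-Hochberg adjustment, which 3 libraries against 3 cannot reach because their smallest exact permutation p is 0.1. Among TE reads, DNA transposons (cut-and-paste elements) made up 34.8% ± 7.21 (SD, n = 3) in female head and 36.4% ± 1.51 (SD, n = 3) in male thorax. Gypsy elements, a family of long terminal repeat (LTR) retrotransposons, made up 32.7% ± 2.51 (SD, n = 3) and 32.5% ± 0.660 (SD, n = 3) in the same groups. LINE elements, retrotransposons without LTRs, made up 18.8% ± 4.69 (SD, n = 3) and 17.8% ± 0.927 (SD, n = 3). A single element, Acol_Tc1_Ele1_DNA_Tc1-Mariner, held 18.5% to 38.5% of a library's TE reads, and the 20 most abundant elements held 74.8% to 88.5%. In female head it was followed by Acol_gypsy_Ele18_LTR_Gypsy with 84.7 ± 8.59 reads per 1000 TE reads (SD, n = 3) and by Acol_CR1_Ele31_LINE_CR1 with 66.0 ± 25.0 (SD, n = 3).

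**Figure D1:**
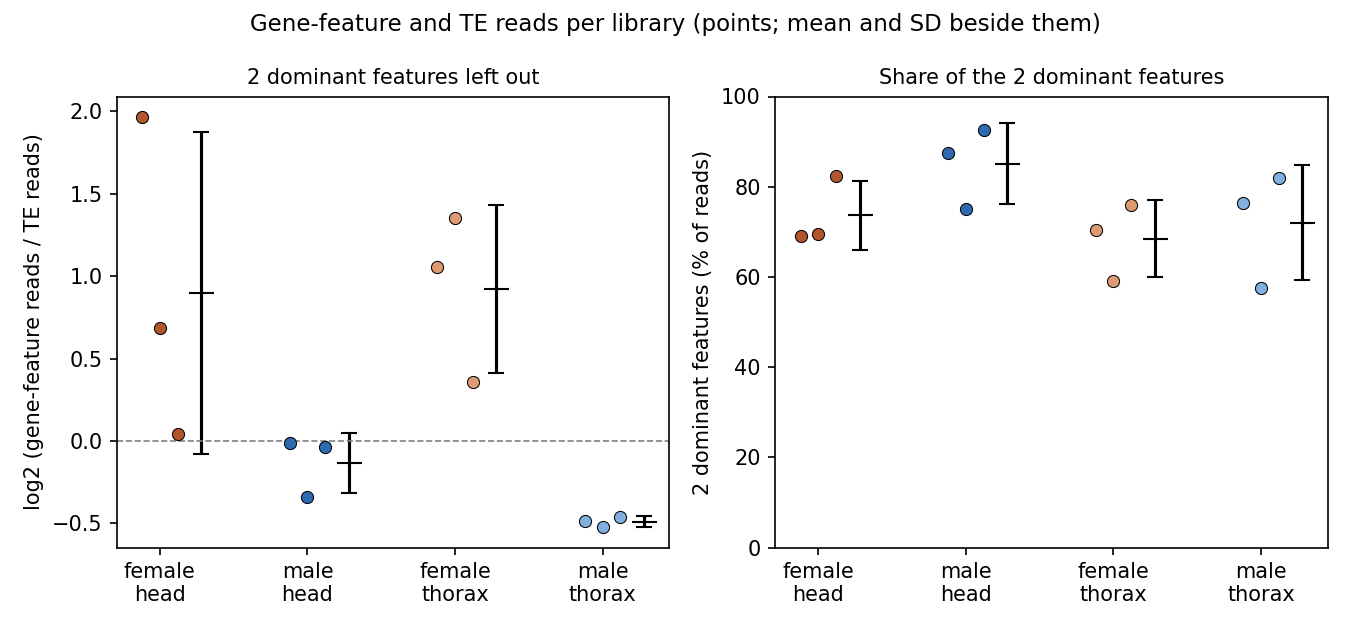
Left, the log2 ratio of gene-feature reads to TE reads in each of the 12 libraries with the 2 dominant features left out; right, the percent of each library's reads in those 2 features. Points are libraries, horizontal bars are means and whiskers SDs (n = 3); the 6 female libraries lie between 0.04 and 1.96 on the left and the 6 male libraries between -0.52 and -0.01.

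In heads, females carried more gene-feature reads relative to TE reads than males once the 2 dominant features were left out. The log2 ratio of gene-feature to TE reads was 0.90 ± 0.98 (SD, n = 3) in females and -0.13 ± 0.18 (SD, n = 3) in males, with each of the 3 female libraries above each of the 3 male libraries (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allow). The difference of 1.03 fell to 0.50 without female head replicate 1. With the 2 dominant features counted, the direction turned, at 2.87 ± 0.52 (SD, n = 3) in females and 3.45 ± 1.09 (SD, n = 3) in males (exact permutation p = 0.4). The median gene feature exceeded the median TE by 2.01 on the log2 fold-change scale of female over male heads. Over both tissues, the median Spearman correlation across 94 TEs was 0.85 for pairs of libraries of different sex, 0.88 within females and 0.89 within males. Across 750 gene features the corresponding medians were 0.27, 0.68 and 0.50, where features are not independent replicates. Over all gene IDs the median count was 8, 11 and 2 in the female head libraries and 0, 3 and 1 in the male head libraries. Sparse counts lower such correlations, so the gene and TE medians cannot be compared with each other. The leaving-out of the dominant features and these correlations were chosen after the data were examined.

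The edgeR quasi-likelihood test with TMM scaling called 318 of 1166 tested features between female and male heads at a Benjamini-Hochberg adjusted p under 0.05. Of these, 185 were higher and 133 lower in females, with 182 gene features and 1 TE among the higher and 87 gene features and 42 TEs among the lower. Scaled to library totals, the same test called 612, with 588 higher and 24 lower, and the median log2 fold change of all features stood at 2.16 instead of 0.46. With that shift of all features towards females, 24 of the 87 gene features lower in females stayed called and 16 turned sign. Of the 42 TEs called lower, 35 stayed called with DESeq2 size factors in edgeR and 6 when scaled to reads outside the 2 dominant features. With library totals 0 stayed called, and the 4 TEs called there were all higher in females. The median TE log2 fold change was then 0.144, and 5 TEs had an unadjusted p under 0.05. The DESeq2 Wald test, with its own size factors instead of library totals, called 27 TEs. Under TMM the lower TEs comprised 13 of 24 BEL-Pao elements (17 adjusted over the list alone), 12 of 34 Gypsy elements (17 adjusted over the list alone), 12 of 22 DNA transposons (13 adjusted over the list alone) and 5 of 24 LINEs (0 adjusted over the list alone). The camera set test with a preset correlation of 0.01 placed all 4 classes below the other features (largest adjusted p = 5.39e-05), and with an estimated correlation none passed (adjusted p = 0.211 for the first 3 classes and adjusted p = 0.249 for LINEs). By fry, a set test of movement on balance one way, no class passed in heads (adjusted p = 0.0744 to 0.0872). The exception among TEs, Acol_mar_Ele25_DNA_Tc1-Mariner of the mariner family, was higher in female heads by a log2 fold change of 2.23 (SE 0.84, edgeR adjusted p = 0.0397). Its level was 1.19 ± 0.806 reads per 1000 TE reads (SD, n = 3) in female heads and 0.174 ± 0.278 (SD, n = 3) in male heads, with overlapping ranges, and it was named after its values were seen. Among gene features, ACMO_003642 had 73 reads in the female and 0 in the male head libraries, at least 19.9-fold higher against a floor of 3 counts over the group, and ACMO_012476 was at least 13.1-fold higher by the same floor (edgeR adjusted p = 0.000232 and 0.00240, the latter 0.0605 without male head replicate 2). In the other direction, ACMO_004647 was 89.4-fold higher in male heads (95% exact interval 15.6 to 3580, 73 reads against 1) and ACMO_005345 was 50.2-fold higher (19.2 to 187), intervals that cover counting error alone. The count of 318 fell to 208 without female head replicate 1, 178 without female head replicate 2 and 128 without male head replicate 2, and the 43 TE calls to 11, 20 and 5.

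In thoraxes the same contrast between gene-feature and TE reads appeared. The log2 ratio without the 2 dominant features was 0.92 ± 0.51 (SD, n = 3) in females and -0.49 ± 0.03 (SD, n = 3) in males, again with no overlap between the sexes (exact permutation p = 0.1, the smallest possible). Over both tissues, permuting sex within each tissue gave an exact permutation p = 0.005 for the difference of 1.22, the smallest that its 400 regroupings allow, with all 6 female libraries above all 6 male libraries. That test treats head and thorax as separate units. With libraries of the same number kept together, a replicate block added after the data were seen, 3 sets against 3 gave an exact permutation p = 0.1, the smallest possible. With the dominant features counted, the difference over both tissues was 0.06 (exact permutation p = 0.86). Without the dominant features, TEs held 32.8% ± 9.37 (SD, n = 6) of the remaining reads in females and 51.3% ± 5.22 (SD, n = 6) in males (exact permutation p = 0.01, 0.02 after adjustment over 10 classes, and 0.1 and 0.167 with libraries of the same number kept together).

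**Figure D2:**
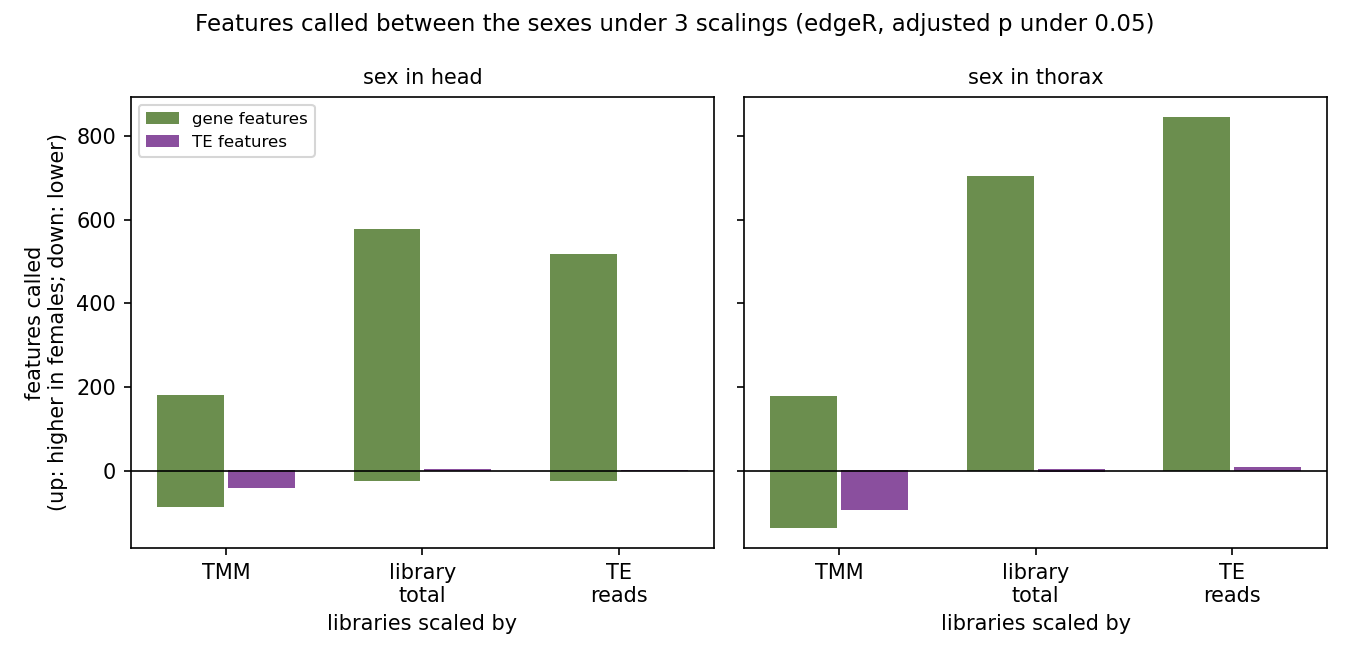
Number of gene features and TEs called between females and males (edgeR, adjusted p under 0.05) in heads and thoraxes, with libraries scaled by TMM, by library totals or by TE reads; bars above 0 count features higher in females and bars below 0 features lower in females. Under TMM 42 and 94 TEs lie below 0, and scaled to TE reads 0 and 1.

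Between female and male thoraxes, edgeR with TMM called 427 features, 184 higher and 243 lower in females. The higher ones held 178 gene features and 1 TE and the lower ones 136 gene features and 94 TEs. Scaled to library totals the test called 722, 717 higher and 5 lower, and the median log2 fold change of all features moved from 0.17 to 2.20. With DESeq2 size factors in edgeR, 323 instead of 178 gene features were higher. The 136 lower gene features became 78 without male thorax replicate 2 and 82 without female thorax replicate 2, and the 427 calls 293 in either case. Of the 136 gene features lower in females, 1 stayed called with library totals and 69 turned sign. Of the 94 TEs lower in females, 89 stayed called with DESeq2 size factors in edgeR, 38 when scaled to reads outside the 2 dominant features, 2 with library totals and 1 relative to TE reads, where 43 turned sign. The gap between the median gene feature and the median TE was 2.81 on the log2 scale. Under TMM, 33 of 34 Gypsy elements (34 adjusted over the list alone), 23 of 24 BEL-Pao elements (23 adjusted over the list alone), 19 of 24 LINEs (19 adjusted over the list alone) and 16 of 22 DNA transposons (17 adjusted over the list alone) were lower in females, together with 2 of 3 Copia elements and the 1 tested SINE. Camera called all 4 classes with 5 or more tested members (largest adjusted p = 1.91e-08), and none passed with an estimated correlation (adjusted p = 0.0903 for each). A list of all 108 tested TEs, added after the data were seen, was lower in females with the estimated correlation as well (camera p = 0.0280). The fry test, which asks whether a class moves on balance one way, gave adjusted p between 0.00182 and 0.00244 on the TMM-scaled counts. It does not compare a class with other features, but its zero is set by the TMM factors, which moved with sex. It was not run with library totals, so it does not bear on the choice of scaling. Acol_gypsy_Ele50_LTR_Gypsy was lower in female thoraxes by edgeR under each of TMM (log2 fold change -4.26, SE 0.66, adjusted p = 1.25e-06), library totals (-2.20) and TE reads (-1.61, adjusted p = 0.0355). Acol_gypsy_Ele22_LTR_Gypsy was lower under TMM (-3.97) and library totals (-1.97) and missed the threshold relative to TE reads (edgeR adjusted p = 0.102). Acol_Pao_Bel_Ele14_LTR_Bel-Pao (-3.78), Acol_gypsy_Ele23_LTR_Gypsy (-3.64) and Acol_Pao_Bel_Ele8_LTR_Bel-Pao (-3.56) were called under TMM but under neither other scaling. A Merged locus (-4.05) was lower under TMM and library totals and missed the threshold relative to TE reads (edgeR adjusted p = 0.137). Acol_mar_Ele25_DNA_Tc1-Mariner was higher in female thoraxes under TMM (2.10, SE 0.61, edgeR adjusted p = 0.00398), with 1.11 ± 0.854 reads per 1000 TE reads (SD, n = 3) against 0.0393 ± 0.0133 (SD, n = 3). Relative to TE reads, a scale added after the data were seen, 10 TEs were higher in female thoraxes, among them Acol_Pao_Bel_Ele7_LTR_Bel-Pao (3.52, edgeR adjusted p = 0.00122), Acol_Outcast_Ele2_LINE_Outcast (2.70, edgeR adjusted p = 0.00361) and Acol_Jockey_Ele1_LINE_Jockey (2.14, edgeR adjusted p = 0.00945). Adjusted over the list alone, 1 BEL-Pao element, 1 LINE, 1 DNA transposon and 0 Gypsy elements stayed higher. Acol_Pao_Bel_Ele7_LTR_Bel-Pao had 16, 35 and 0 reads in the female and 1, 4 and 1 in the male thorax libraries, which overlap. Among gene features, ACMO_012532 was at least 59.4-fold and ACMO_001610 at least 15.2-fold higher in female thoraxes against the floor of 3 counts over the male group (edgeR adjusted p = 2.06e-06 and 0.00275).

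The sex calls of both tissues overlapped. They share no library but come from the same fit, with TMM factors that moved with sex and female libraries taken as paired across tissues. Of the 185 features higher in female heads and 184 higher in female thoraxes, 100 were shared where 29.2 would be by chance (Fisher's exact test p = 1.34e-42 over 1166 features, which are not independent). These 100 held 97 gene features. With library totals, the 588 and 717 higher features shared 531 against 362 by chance. Scaled to TE reads, 526 and 866 shared 515 against 391. Larger numbers of calls cap the ratio of shared to chance features, so these ratios cannot be compared between scalings. The lower features shared 99 against 27.7 by chance under TMM, of which 39 were TEs, and with library totals they shared 0 of 24 and 5.

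Between female head and female thorax few features differed. EdgeR with TMM called 10, with 9 higher in head and 1 higher in thorax, and the 4 TEs among them were Gypsy elements higher in head. Acol_gypsy_Ele50_LTR_Gypsy rose the most of these, with a log2 fold change of 3.92 (SE 0.66, edgeR adjusted p = 1.71e-05) and 5.62 ± 3.95 reads per 1000 TE reads (SD, n = 3) in head against 0.302 ± 0.175 (SD, n = 3) in thorax. Acol_gypsy_Ele31_LTR_Gypsy (2.82, edgeR adjusted p = 0.0107) had 13.5 ± 3.62 reads per 1000 TE reads (SD, n = 3) in head against 2.22 ± 0.398 (SD, n = 3) in thorax. Acol_gypsy_Ele32_LTR_Gypsy (2.51, edgeR adjusted p = 0.00612) had 3.10 ± 0.526 (SD, n = 3) against 0.669 ± 0.132 (SD, n = 3). The remaining one, Acol_gypsy_Ele88_LTR_Gypsy (2.80, edgeR adjusted p = 0.0466), was named after its values were seen and lost its call both under library totals and relative to TE reads. Acol_gypsy_Ele50_LTR_Gypsy stayed called under library totals and relative to TE reads, Acol_gypsy_Ele31_LTR_Gypsy under the latter alone (edgeR adjusted p = 0.1 and 0.00134), and Acol_gypsy_Ele32_LTR_Gypsy under neither (edgeR adjusted p = 0.823 and 0.277). Among gene features higher in head, ACMO_009096 had 489 reads against 4, a 221-fold ratio per counted read (95% exact interval 85.8 to 814), and ACMO_008502 had 78 against 1, a ratio of 141 (24.6 to 5640). The log2 ratio of gene-feature to TE reads did not separate the tissues, at 0.90 ± 0.98 in head and 0.92 ± 0.51 in thorax (SD, n = 3 each, exact permutation p = 1). Camera called Gypsy and LINE elements as higher in head (largest adjusted p = 0.0278), and neither passed with an estimated correlation (adjusted p = 0.810). Under library totals 5 features were called, and with those 2 groups alone in the fit 3 features; the 4 TE calls fell to 2 without female head replicate 2, female head replicate 3 or female thorax replicate 2.

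Between male head and male thorax, edgeR with TMM called 59 features, 34 higher in head and 25 higher in thorax. The head side held 33 gene features and a single TE, Acol_gypsy_Ele50_LTR_Gypsy, at 9.69 ± 2.68 reads per 1000 TE reads (SD, n = 3) in head against 1.02 ± 0.164 (SD, n = 3) in thorax, which was named after its values were seen and missed the threshold under library totals (edgeR adjusted p = 0.1). The thorax side held 13 gene features and 11 TEs, among them Acol_gypsy_Ele47_LTR_Gypsy (log2 fold change -3.56, SE 0.82, edgeR adjusted p = 0.00266) and 1 of 3 Copia elements. Acol_gypsy_Ele47_LTR_Gypsy missed the threshold relative to TE reads (edgeR adjusted p = 0.293). The Copia element, Acol_copia_Ele10_LTR_Copia, had 12.4 ± 0.196 reads per 1000 TE reads (SD, n = 3) in male thorax and 4.42 ± 1.51 (SD, n = 3) in male head. Relative to TE reads, 6 TEs were higher in head and 0 in thorax, where 26 TEs had an unadjusted p under 0.05 by edgeR and DESeq2 with its own size factors was not run on that scale. The 6 included Acol_gypsy_Ele88_LTR_Gypsy (4.09), Acol_gypsy_Ele50_LTR_Gypsy (3.24), Acol_gypsy_Ele31_LTR_Gypsy (2.14) and Acol_R1_Ele16_LINE_R1 (1.64), the last a LINE of a family that inserts into ribosomal DNA. Among gene features, ACMO_000285 was 199-fold higher in head (95% exact interval 54.1 to 1653, 165 reads against 2) and ACMO_001052 had 82 reads against 1, a ratio of 197 (34.4 to 7887). ACMO_010319 was at least 11.2-fold higher in thorax against the floor of 3 counts over the group, and ACMO_004294 had 63 reads in thorax against 1 in head, a ratio of 26.2 (4.53 to 1050, edgeR adjusted p = 0.00112, 0.155 relative to TE reads). Camera called BEL-Pao, Gypsy and LINE elements as lower in head (largest adjusted p = 0.0483), and none passed with an estimated correlation (adjusted p = 0.669). Without male head replicate 2 the balance turned to thorax, with 20 features higher in head and 73 higher in thorax, the latter including all 38 TEs called. The count of 59 became 93 without that library and 31 under library totals, and the 12 TE calls became 38 without male head replicate 2, 4 without male head replicate 1 or 3, 5 without male thorax replicate 1 and 6 without male thorax replicate 2.

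**Figure D3:**
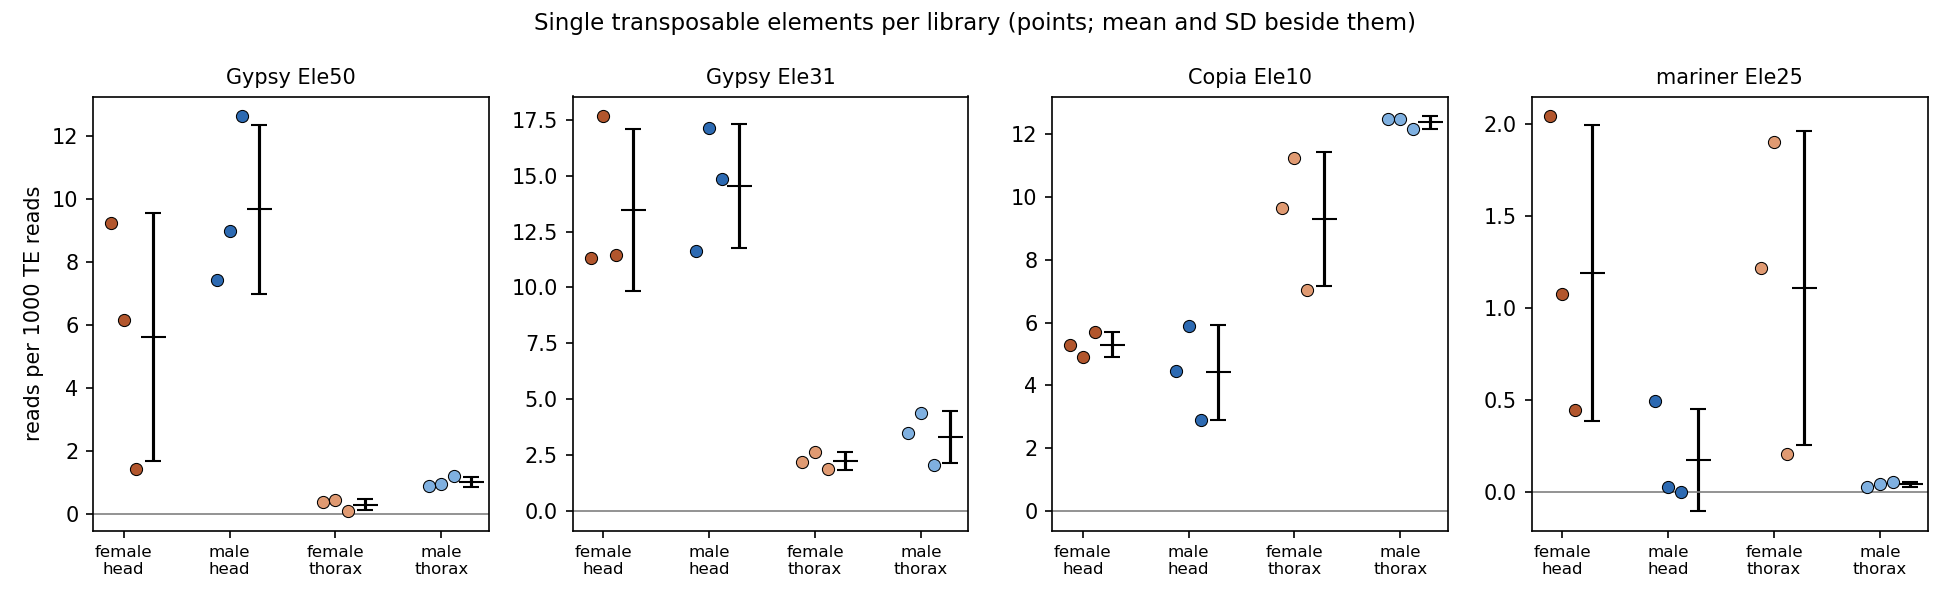
Reads per 1000 TE reads of 4 elements in each library of the 4 groups; points are libraries, horizontal bars means and whiskers SDs (n = 3). The Gypsy elements Ele50 and Ele31 lie higher in head than in thorax in both sexes, Copia Ele10 lies higher in thorax, and mariner Ele25 has a higher mean in females.

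The tissue calls of the sexes, again from separate libraries in the same fit, shared 4 of the 9 and 34 features higher in head, where 0.262 would be shared by chance (Fisher's exact test p = 6.87e-05). Over both sexes, Copia elements held 0.640% ± 0.0934 (SD, n = 6) of TE reads in head and 1.20% ± 0.216 (SD, n = 6) in thorax (exact permutation within sex p = 0.005, 0.0175 after adjustment over 7 classes). Most of this lay in Acol_copia_Ele10_LTR_Copia, with 5.29 ± 0.392 reads per 1000 TE reads in female head and 4.42 ± 1.51 in male head. It had 9.31 ± 2.13 in female thorax and 12.4 ± 0.196 in male thorax (SD, n = 3 each), so the Copia result rests largely on a single element. BEL-Pao elements held 13.9% ± 1.55 (SD, n = 6) in head and 11.5% ± 1.10 (SD, n = 6) in thorax (exact permutation p = 0.005, 0.0175 after adjustment). Without the 2 libraries under 100000 reads the differences were -0.618 percentage points for Copia (-0.555 with all libraries) and 2.02 for BEL-Pao (2.35). Both then missed the adjusted threshold (0.07 and 0.14, by the same exact permutation with 100 instead of 400 regroupings), and BEL-Pao also without the most abundant TE (0.105). With libraries of the same number kept together in the females and male libraries regrouped freely, both passed (0.0292 each). So did DNA transposons, lower in head by 3.63 percentage points (adjusted 0.315 by the test of single libraries) but higher by 1.44 without the most abundant TE. Male libraries also matched best with their own number, so these 0.0292 values depend on leaving them unpaired. Pairing them as well would raise the smallest possible p and was not run. By the test of single libraries the other classes did not pass, with SINEs at 0.126% ± 0.0766 and 0.0521% ± 0.0183 (SD, n = 6, adjusted exact permutation p = 0.0933).

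The sex difference depended on tissue for 8 features by the edgeR interaction term with TMM. For 7 gene features the mean was highest in male heads. ACMO_005345 had a mean of 283 ± 155 CPM (SD, n = 3) in male head, 8.22 ± 11.7 in female head, 7.63 ± 3.61 in female thorax and 4.09 ± 0.922 in male thorax, with an interaction of -5.56 (SE 1.25, edgeR adjusted p = 0.0108). ACMO_001566 had 406 ± 227 CPM (SD, n = 3) in male head and means of 14.9 to 36.6 in the other groups, with an interaction of -5.15 (SE 1.13, edgeR adjusted p = 0.0160). Without male head replicate 2 the latter missed the threshold (edgeR adjusted p = 0.0686). The 1 TE, Acol_gypsy_Ele37_LTR_Gypsy, had an interaction of 2.89 (SE 0.76, edgeR adjusted p = 0.0401), and under library totals its interaction was 2.72 without a call (adjusted p = 0.998). With replicate number as a block among the female libraries, an alternative added after the data were seen, 13 features were called for the interaction. The count of 8 ranged from 0 without female head replicate 2 to 28 without male head replicate 2, of which 25 (15 of them TEs) had the opposite direction to the 7 gene features, and was 2 without male thorax replicate 1, 4 without female head replicate 3 or male thorax replicate 2 and 5 without female thorax replicate 1. Camera called Gypsy, BEL-Pao and LINE elements for the interaction (largest adjusted p = 0.000614), and none passed with an estimated correlation (smallest adjusted p = 0.396).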

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

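The tests of scaling and of other splits of the libraries were chosen after their results were seen, and the bounds of the scaling test were set with its value known; the test of a single divergent male head library was written beforehand. The sex difference was not the same in head and thorax for 8 features, by the interaction term of the edgeR fit. The log2 interaction was 2.89 for Acol_gypsy_Ele37_LTR_Gypsy, -5.56 for ACMO_005345 and -5.15 for ACMO_001566.

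The 7 gene features of this set had higher counts in male head than in each other group. Of the 7, 6 had each male head library above every female head and male thorax library as a share of reads. Features picked by this contrast lean that way, so this could not decide whether a single divergent male head library plays a part. Leaving out male head replicate 2 kept 3 of the 7 called, with 25 of the 28 calls then in the opposite direction, and leaving out either other male head library kept 7. Composition scaling, which moves all features alike, was argued against as the whole of these interactions. The 4 other scalings shifted the median interaction of all features by at most 0.889 (log2), against interactions of -3.40 or lower. Of the 7, 5 stayed called with library totals, 5 with TE reads and 7 with reads outside the 2 dominant features, under shifts that favour this direction. A difference of sex and tissue stays open, as untested.

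Chance could not be excluded for the number of interaction calls: of 100 drawn splits of the 12 libraries, 5 (the real one included) called 8 or more, and the highest other split called 101. What sets that split apart from the others was not tested. The drawn splits took no account of the female pairs, and the fit with a replicate block in females was not split in this way. For the pairwise counts, 3 libraries against 3 make 10 splits, too few for a share under 0.05. The real split, which was the 1 split reaching its own count in each comparison, called 318 features for sex in head against 3 for the highest other split, 427 for sex in thorax against 0, 10 for tissue in females against 3, and 59 for tissue in males against 0. Replicate numbers were taken to pair the female libraries, and of the 4 splits that part all 3 pairs the real one called 10 and the highest other 0. The 6 other splits, with up to 3 calls, each leave libraries of the same number on the same side.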

How the results depend on the processing

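Scaling to TE reads or to reads outside the 2 dominant features, leaving out the 2 libraries under 100000 reads, the 2 dominant features or the most abundant TE, all settings of the gene-to-TE ratio, TE composition and single TEs relative to TE reads, a list of all TEs, the replicate blocks in females and in permutations, and list tests with a replicate left out were chosen after the data were seen. Of the features named by the rule for their changes, the tally covered the TEs and the 2 largest changes per direction and comparison, not the others. Over these, 389 log2 fold changes kept direction and side of the threshold, 49 kept direction and lost the threshold and 0 turned. Of the values relative to TE reads, 143 kept both and 55 lost the threshold. Of the list tests, 204 kept the side of the threshold, 29 lost and 7 gained it. Direction was not compared where a list passed in neither setting. Features with few reads limit what can be called, since a count of 0 allows up to 40.6 CPM in the shallowest library. With the replicate block in females, where numbers were taken to pair the libraries, 15 features and 4 TEs were called for tissue in females and 13 features and 2 TEs for the interaction. No call of a feature in that tally or of a list changed. With libraries of the same number kept together in a replicate block, permutation p for the log2 gene-to-TE ratio by sex over both tissues (difference 1.22) went from 0.005 to 0.1, the smallest possible, and DNA transposons by tissue (-3.63 points) passed at 0.0292 adjusted. The TE share of reads outside the 2 dominant features by sex, 0.02 adjusted, was lost under it (0.167), as were the 5 other classes that had passed on that scale (0.167 each), where 0.1 is the smallest unadjusted p. Male head and thorax libraries of the same number correlated from 0.0627 to 0.166, each best with its own number. They were not taken as paired by tissue, where their regrouping gave 160 arrangements and a smallest p of 0.0125. Pairing them as well would leave fewer arrangements and a larger smallest p, and was not run. The 0.0292 values by tissue therefore depend on this choice. Pairs across the sexes correlated from -0.181 to 0.0436, none best with its own number. Tests by strand were not run because the files do not separate it, and pseudocounts do not apply to counts. Except where a setting's construction shows it, the cause of each change was not tested.

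Under TMM the counts in the order sex in head, sex in thorax, tissue in females, tissue in males and interaction were 318, 427, 10, 59 and 8 features and 43, 95, 4, 12 and 1 TEs. With library total only, the first 4 were 612, 722, 5 and 31 features, and the TEs 4, 6, 1, 3 and 0. Scaled to TE reads, the sex counts were 550 and 868 features, and the TEs 3, 11, 2, 6 and 0. Scaled to reads outside the 2 dominant features, 830 features were called for sex in thorax, 89 for tissue in males and 17 for the interaction, with 9, 43 and 0 TEs for sex in head, sex in thorax and interaction. With only the 2 groups compared, 149 features were called for sex in head, 3 for tissue in females and 89 for tissue in males, with 9, 1 and 31 TEs. With no filter, 17 features were called for tissue in females and 5 for the interaction, with 17, 150 and 0 TEs for sex in head, sex in thorax and interaction, and the gap between the median gene feature and median TE in thorax was 2.24 instead of 2.81. With a mean of at least 10 CPM, tissue in females had 17 features and the interaction 2 TEs. With limma-voom, tissue in females had 6 features and 1 TE and the interaction 3 features and 0 TEs. With DESeq2 size factors (RLE) the interaction had 13 features and 2 TEs, and the DESeq2 Wald test called 27 TEs for sex in head and 0 for the interaction. With the replicate block the 5 counts were 312, 403, 13, 76 and 11, and the interaction had 2 TEs. Without the 2 libraries under 100000 reads, 7 TEs were called for tissue in males and 0 for the interaction. With an estimated correlation, 0 lists were called in each comparison instead of 4, 4, 2, 3 and 3, and the list of all TEs gave p = 0.0280 for sex in thorax.

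Differences of class shares are in percentage points, first group minus second. Without the most abundant feature, sex in head gave 10.9 for gene features, -7.84 for Merged loci and -3.03 for TEs (-9.96, 9.07 and 0.892 with all features), and tissue in males -4.41 for gene features and 15.0 for Merged loci (9.48 and -1.16). Without the 10 most abundant features, sex in head gave 16.9, -0.206 and -16.7, Merged loci 2.55 for sex in thorax, -0.942 for tissue in females and 1.82 for tissue in males, and TEs 2.74 for tissue in females. Without the 2 dominant features, sex in head gave 16.1, -1.71 and -14.4, Merged loci 0.910 for sex in thorax and 4.45 for tissue in males, and TEs 0.124 for tissue in females. Without the 2 libraries under 100000 reads, TEs gave -0.000694 for sex in head and Merged loci 0.305 for sex in thorax. In TE composition over both sexes, that setting gave 2.02 for BEL-Pao, -0.618 for Copia and -0.417 for LINEs by tissue. Without the most abundant TE, Gypsy gave 0.00832 by sex and -1.78 by tissue, and by tissue BEL-Pao gave 1.97, LINEs -0.876 and DNA transposons 1.44. With the 2 dominant features, the log2 gene-to-TE ratio differed by -0.59 for sex in head, 0.14 for tissue in females and 0.0611 for sex over both tissues; without the 2 libraries under 100000 reads it differed by -0.00293 for tissue over both sexes.

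With each replicate left out in turn, features called ranged from 128 to 355 for sex in head (128 without male head replicate 2, 178 without female head replicate 2 and 208 without female head replicate 1), 40 to 93 for tissue in males (93 without male head replicate 2) and 0 to 28 for the interaction (0 without female head replicate 2, 28 without male head replicate 2). TEs ranged from 5 to 39 for sex in head, 2 to 5 for tissue in females, 4 to 38 for tissue in males and 0 to 15 for the interaction, with 5, 38 and 15 reached without male head replicate 2. Lists called for tissue in females ranged from 1 (without female head replicate 3 or female thorax replicate 2) to 4 (without female head replicate 1). Share differences ranged from -1.04 to 3.72 for TEs by sex in head, -3.11 to 1.67 for Merged loci by sex in thorax and -5.74 to 1.94 for Merged loci by tissue in males. In TE composition, they ranged by sex from -0.778 to 1.58 for LINEs and -0.0503 to 3.36 for DNA transposons, and by tissue from 1.95 to 2.75 for BEL-Pao, -0.625 to -0.501 for Copia, -0.554 to 1.94 for LINEs and -5.68 to -1.83 for DNA transposons. BEL-Pao lost the adjusted threshold in some of these, where fewer regroupings raise the smallest p. The log2 gene-to-TE ratio ranged from 0.50 (without female head replicate 1) to 1.46 for sex in head, -0.56 to 0.40 for tissue in females and -0.10 to 0.38 for tissue over both sexes.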

Other observations

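The tests below were chosen after the results they bear on had been seen, and the bounds of the tests of dominant features, depth and scaling were set with their values known. Gene-feature profiles correlated less between the sexes than within females also with gene-feature reads thinned to the same number. With 4003 such reads per library, the Spearman correlation across 750 gene features was 0.427 to 0.590 within females, 0.209 to 0.490 within males and 0.0853 to 0.316 between the sexes, so the last 2 ranges overlap. With TE reads thinned to 4041 per library, the medians across 94 TEs were 0.82 within females, 0.84 within males and 0.81 between the sexes. Similar totals fell on far more gene features than TEs, so the gene and TE values still differ in reads per feature.

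The excess of gene-feature over TE reads in females was weighed against 3 technical explanations. Depth as the sole cause was argued against: the ratio separated all 36 pairs of a female and a male library, but the female library had more total reads in 20 of them. Reads of the 2 dominant features are left out of the ratio, so by construction they cannot carry its excess. The gap between the median gene feature and median TE was at least 1.67 in both sex contrasts under each setting run. It is no test of those 2 features, since they hardly move such medians and scaling shifts all features nearly alike. The gap shows only that the excess was not limited to a few features. An effect of the share of the 2 features cannot be told apart, as it was lower in the female library in 26 of the 36 pairs. RNA of a single female source added in varying amounts cannot be told apart from other shared variation, as the first principal component held 92.4% of the variance within female groups for 63 female-high gene features and 90.8% for 48 gene features called in neither sex comparison. A difference between the sexes themselves remains open and untested.

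Whether the TEs called lower in females under TMM reflect composition scaling cannot be told apart from a loss of TE reads. In simulated counts, all gene features except the dominant one were raised 4-fold in females and TEs were left unchanged. Library sizes were multiplied there by the TMM factors, which moved with sex. The 2 dominant features were given the same mean level relative to that size in each library. The data differ in both, so the simulated numbers of calls need not carry over to them. TMM then called 56 of 83 TEs lower for sex in head and 70 for sex in thorax, against 6 and 2 with library totals. The simulated gap between the median gene feature and median TE was 2.02 and 1.96, against 2.01 and 2.81 in the data. Thus TMM can give such calls without a change of TEs. Of the 94 TEs called lower in female thorax, 38 stayed called lower when libraries were scaled to reads outside the 2 dominant features, 2 with library totals and 89 with DESeq2 size factors, which share the assumption of TMM that most features do not change. Scaling to TE reads sets their sum equal by construction, so the 1 TE that stayed called there does not bear on this.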
